A study of Mus musculus with 72 samples.

How the data were processed

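The series holds 72 mouse samples, of which 12 are RNA-seq libraries of bone-marrow-derived macrophages and 60 are ChIP-seq or ATAC-seq samples that were not analysed here. Per the labels' protocols, marrow cells of C57BL/6J mice were differentiated for 6 days with M-CSF from L929 cell supernatant, replated, and given IL-4 at 20 ng/ml for 24 h or left untreated. One label field gives the IL-4 concentration per microlitre and the others per millilitre. Poly-A RNA was fragmented, primed with random primers and made into libraries with a TruSeq RNA kit for an Illumina HiSeq instrument, per the labels' protocols, which do not state whether strand was kept. Reads of antisense or overlapping genes may therefore be shared, and so may reads of near-identical copies such as the Chil3 and Chil4, Ifit3 and Ifit3b, Rnase2a and Apol7 genes.

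The authors deposited one table of whole-number read counts per gene with no normalization and one table of a signal per gene made from them. Per the submitters' processing notes, HISAT2, featureCounts and edgeR were among the tools used and mm10 was the genome build; tool versions, settings and the gene annotation are not given in the sources used here. In the second deposited table, each signal was the count multiplied by 1 constant per library, with a largest relative deviation of 5.1e-15, so that its column sums ran from 943762 to 1065714. Both tables list 55450 gene identifiers, and all 55450 matched a symbol. Gene positions are those of a RefSeq table of GRCm38.p6, the same build as mm10.

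The labels place the 12 libraries in 4 groups of 3, wild type and Egr2KO, each untreated or with IL-4. They do not say whether replicates came from separate mice or cultures, so p-values measure the spread between these samples, which may be technical. No pair of replicates agreed within sampling noise: the chi-square statistic per degree of freedom between replicates of a group, over genes with at least 20 reads per pair, ran from 7.15 to 26.7 with a median of 12.5. The groups, the tests, the rule for named genes, the gene lists and most alternatives were set before the data were examined.

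The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) on the counts, with robust estimation, TMM scaling and filterByExpr at a minimum count of 10 and a minimum total of 15, which kept 18016 genes. All 12 libraries were fitted together with 1 coefficient per group, and 5 contrasts were tested: IL-4 against untreated in each genotype, Egr2KO against wild type without and with IL-4, and the difference between the genotypes' IL-4 effects. The last is the log2 fold change in Egr2KO minus that in wild type. P-values were adjusted by Benjamini-Hochberg over all genes tested and called below 0.05. Levels are CPM, with library totals scaled by TMM, and standard errors were derived from the fold change and its F statistic. Where the lower group held 0 reads over its 3 libraries, the fold was computed against a floor of 3 reads over the group and is a lower bound; with 1 to 3 reads, the ratio is given with its exact 95% interval. Intervals and floors cover counting error only, because PCR copies are not independent molecules.

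The text names Egr2; the 6 largest rises and 6 largest falls of each contrast among called genes with a mean of at least 5 CPM in the higher group, a named symbol and, except for the difference between genotypes, no overlap between the 3 libraries of each group; members of the gene lists, up to 3 per list and contrast with the smallest p, or up to 2 of highest CPM where none was called; any marker of alternative activation; and Xist, Ddx3y, Eif2s3y, Kdm5d, Uty and the mitochondrial genes as checks. Genes outside this rule are said to be so where they appear.

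The 25 lists covered alternative activation markers, IL-4 and STAT6 signalling, the EGR family with NAB co-repressors, lipid uptake and fatty acid oxidation, cholesterol synthesis, inflammatory cytokines and NF-kB targets, interferon-stimulated genes, MHC class II and co-stimulation, macrophage identity, complement and clearance of dead cells, cell fusion and osteoclast genes, arginine and polyamine metabolism, glycolysis and hypoxia targets, the unfolded protein and integrated stress response, cell cycle, transcriptional cofactors, immediate-early genes, and markers of neutrophils, eosinophils, mast cells, dendritic cells, T and NK cells, B cells, fibroblasts and erythroid cells. Arg1, Cd209a and Il4ra each stand in 2 lists. Lists were tested against all other genes with camera at a preset inter-gene correlation of 0.01, with adjustment over the lists of a contrast. Members past the low-count filter are called measured, and were also counted with p-values adjusted over the list alone.

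Whether replicate numbers pair the libraries was checked from correlations of deviations from the group means. Between untreated and IL-4-treated Egr2KO libraries these were 0.25, 0.21 and 0.28 for numbers 1, 2 and 3. All passed the preset minimum of 0.1, so these numbers were taken as pairs, though the main fit is unpaired. The other group pairs did not pass it for every number.

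The test was tried on simulated counts for the same 18016 genes and library sizes, with 200 genes changed. For the wild-type IL-4 contrast, 56% of genes changed 1.5-fold, 80% of those changed 2-fold, 100% of those changed 4-fold and 60% of those lowered to 0.5-fold were called, with 5.13% of calls false. For the genotype contrast with IL-4 the shares were 54%, 82%, 98% and 58%, with 7.59% false, and for the difference between genotypes 26%, 62%, 84% and 46%, with 6.84% false.

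The alternatives were RLE size factors, library totals alone, DESeq2 1.42.0, no filter on low counts, a stricter filter of 1 CPM in 3 libraries, the replicate number as a block, a fit of only the 2 compared groups, limma-trend on log2 of the authors' deposited signal plus 1 or plus 0.1, leaving out each library in turn, and for lists an estimated correlation, the block and fry. After the data had been seen, 2 more were added: the deepest library thinned to 21091044 reads, and a replicate block within each genotype.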

Results

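RNA-seq was analysed in 12 libraries of mouse bone-marrow-derived macrophages, which are macrophages grown from marrow cells in culture. The libraries formed 4 groups of 3, wild type and Egr2KO, each untreated or with IL-4. IL-4 is a cytokine that activates the transcription factor STAT6 and gives the state called alternative polarization, and Egr2 encodes a zinc-finger transcription factor. The title of the series asks how EGR2 links STAT6 activation to that state. The 3 untreated wild-type libraries held 73577433, 16890120 and 15467933 counted reads, and the wild-type IL-4 libraries 17688269, 22351350 and 19915367. The untreated Egr2KO libraries held 21091044, 24189095 and 26535629 and the Egr2KO IL-4 libraries 20675079, 21655396 and 21780321. The deepest library, untreated wild-type replicate 1, held 3.49 times the median of the other 11.

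Library composition was measured in all 12 libraries. Mitochondrial genes took 1.07% to 1.54% of reads, ribosomal protein genes 2.84% to 3.74% and the 10 most abundant genes 8.36% to 9.75%. Xist, the transcript of the inactive X chromosome, lay at 0 to 0.0948 CPM by library totals, and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty lay at 7.89 to 24.4, 21.6 to 39.2, 14.6 to 27 and 7.74 to 20.0 CPM. The first principal component took 47.3% of the variance and the second 29.3%. The median biological coefficient of variation was 0.102.

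Egr2 (ENSMUSG00000037868.15, mm10 chromosome 10, 67534469 to 67542188) was measured first as a check of the genotype labels. In wild type it lay at 40.6 ± 5.40 CPM (SD, n = 3, as for all values given as mean ± SD) without IL-4 and 182 ± 9.36 CPM with IL-4, a log2 rise of 2.17 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.000388). In the Egr2KO libraries it lay at 0.569 ± 0.873 CPM without IL-4 and 1.76 ± 0.203 CPM with IL-4. The log2 change from wild type to Egr2KO was -6.03 without IL-4 (adjusted p = 9.41e-05; -9.19 without untreated Egr2KO replicate 3) and -6.69 with IL-4 (adjusted p = 8.90e-07). The untreated Egr2KO replicates 1, 2 and 3 held 2, 1 and 43 Egr2 reads, and the IL-4-treated ones 37, 35 and 44. The log2 change of Egr2 with IL-4 in the knockout was 1.5 and was not called (adjusted p = 0.173), but without untreated Egr2KO replicate 3 it was 4.67 (adjusted p = 7.19e-07); over all 17 alternatives the adjusted p ran from 7.19e-07 to 0.345. The difference between the genotypes' IL-4 effects on Egr2 was -0.66 and was not called (adjusted p = 0.612), and without that library it was 2.50 (adjusted p = 0.0032; range over 22 alternatives 0.0032 to 0.873). The labels name a floxed allele without the deleted part, so reads from exons outside it would count here too. Retnla, a secreted protein of alternatively activated macrophages, lay at 0.857, 0.409 and 17.9 CPM in the untreated Egr2KO replicates 1, 2 and 3.

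**Figure D1:**
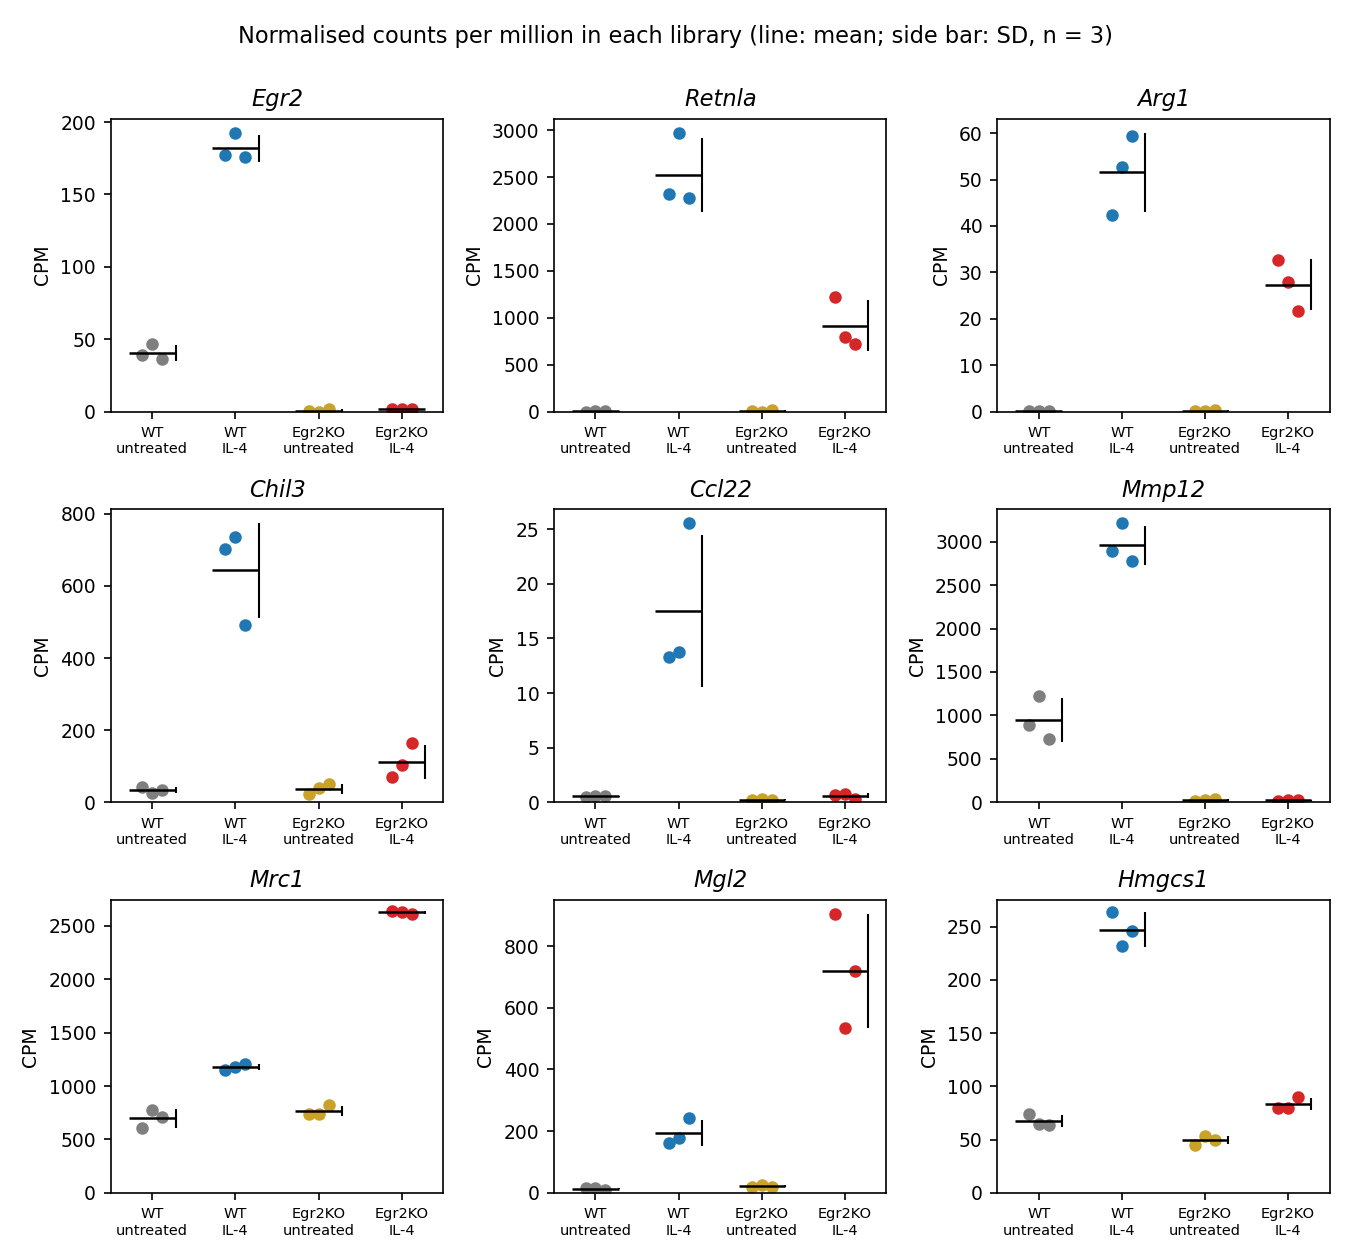
Normalised counts (vertical axes, CPM, linear from 0) of 9 genes in the 12 libraries of 4 groups; each point is 1 library, horizontal lines are group means and side bars SD (n = 3). Egr2 averaged 182 CPM in wild type with IL-4 and 1.76 CPM in Egr2KO with IL-4, Mmp12 averaged 2959 and 21.1 CPM, and Mrc1 averaged 1178 and 2626 CPM.

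What IL-4 does in wild-type macrophages was the first comparison. Retnla rose from 1.04 ± 0.97 to 2522 ± 392 CPM and Arg1, the arginase that defines this state in mice, from 0.0917 ± 0.0557 to 51.5 ± 8.59 CPM. Rnase2a, an eosinophil-type ribonuclease gene with close copies, rose from 0.678 ± 0.864 to 271 ± 149 CPM. The ion channel genes Scn3a and Kcnd3 and the tight-junction gene Cldn11 rose from 3, 1 and 2 reads over 3 libraries to 38.3 ± 4.05, 7.63 ± 0.0968 and 8.07 ± 1.35 CPM. The ratios were 1335 (95% counting interval 456 to 6479), 798 (142 to 31596) and 418 (115 to 3458). Cx3cr1, the fractalkine receptor, fell from 17.4 ± 7.10 to 0.140 ± 0.0201 CPM. Adgre4, an adhesion receptor related to F4/80, fell from 21.3 ± 5.51 to 0.497 ± 0.212, and Siglece, an inhibitory sialic acid receptor, from 6.47 ± 0.263 to 0.218 ± 0.162. The interferon-induced genes Cxcl10, Ifit3 and Ifit3b fell from 7.07 ± 2.30, 49.0 ± 22.6 and 30.6 ± 14.2 to 0.191 ± 0.161, 1.97 ± 0.579 and 1.10 ± 0.271 CPM. Without untreated wild-type replicate 1 the log2 change of Scn3a went from 10.14 to 8.57, of Kcnd3 from 9.04 to 10.30, of Cldn11 from 8.38 to 7.74, of Arg1 from 9.68 to 8.61 and of Rnase2a from 9.27 to 8.2. Without replicate 3 that of Scn3a was 12.96, of Cldn11 8.97 and of Rnase2a 10.52. Without IL-4-treated replicate 3 that of Cxcl10 went from -5.11 to -5.95, and without replicate 2 that of Siglece from -4.80 to -5.51.

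Of 18016 genes tested in wild type with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 3748 were higher and 3680 lower with IL-4, and 824 and 1172 of these changed at least 2-fold. Log2 changes of the 6 largest rises ran from 8.38 (SE 0.35) for Cldn11 to 11.83 (SE 1.45) for Retnla, with adjusted p = 5.56e-11 and 0.000231. Those of the 6 largest falls ran from -6.89 (SE 0.43) for Cx3cr1 to -4.61 (SE 0.49) for Ifit3, with adjusted p = 4.05e-08 and 5.60e-05. Without untreated wild-type replicates 1 or 3 the log2 changes were 10.75 and 12.79 for Retnla and 7.74 and 8.97 for Cldn11, all called.

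Alternative activation markers rose as a group in wild type, with 20 of 24 measured members higher, 3 lower and the same counts adjusted over the list alone. Chil3, a chitinase-like secreted protein, rose from 34.5 ± 7.84 to 643 ± 132 CPM and the chemokine Ccl22 from 0.523 ± 0.0623 to 17.5 ± 6.95. Rises were also called for the lectin Mgl2 from 13.5 ± 2.57 to 194 ± 42.7, the mannose receptor Mrc1 from 697 ± 86.7 to 1178 ± 29.2 and the nuclear receptor Pparg from 53.4 ± 4.37 to 133 ± 8.88. Il4ra, the IL-4 receptor chain, fell from 88.2 ± 16.0 to 60.8 ± 4.54 CPM (log2 -0.53, edgeR adjusted p = 0.000881). Tgm2 lay at 32.5 ± 1.72 and 43.4 ± 0.974 CPM and was not called (edgeR adjusted p = 0.215). In 15 of 17 alternatives it was not called either (adjusted p from 0.00157 to 0.431, called when only these 2 groups were fitted, the lowest, and with the block within each genotype, at 0.00212). The list's median log2 change was 4.02 (camera adjusted p = 4.90e-10, and adjusted p = 0.0712 with an estimated correlation). None of the wild-type list calls below stood with that correlation either.

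Cholesterol synthesis genes rose in wild type for 19 of 20 members, with none lower and the same counts adjusted over the list alone. The mevalonate-pathway enzymes Hmgcs1 and Mvd rose from 67.7 ± 5.76 to 247 ± 16.4 and from 16.7 ± 2.27 to 90.8 ± 14.2 CPM. The median was 1.49 (camera adjusted p = 5.97e-14, and adjusted p = 0.0829 with an estimated correlation). Lipid uptake and oxidation genes rose for 12 of 17 and fell for 0, adjusted over the list alone likewise. Plin2, a lipid droplet coat protein, rose from 900.2 ± 25.2 to 1289 ± 16.4 CPM. The median was 0.42 (camera adjusted p = 4.33e-05, and adjusted p = 0.0757 with an estimated correlation). The unfolded protein list had 11 of 14 higher and 1 lower, 12 and 1 adjusted over the list alone. The endoplasmic reticulum chaperone Hspa5 lay at 525 ± 15.5 and 1122 ± 54.2 CPM and Pdia4, a disulfide isomerase, at 77.6 ± 3.06 and 302 ± 11.6. The median was 0.93 (camera adjusted p = 1.24e-05, and adjusted p = 0.0712 with an estimated correlation). Arginine and polyamine genes had 9 of 13 higher and 1 lower, the same adjusted over the list alone, and the arginine transporter Slc7a2 rose from 1.28 ± 0.391 to 88.2 ± 8.21 CPM. The median was 0.56 (camera adjusted p = 0.00287, and adjusted p = 0.0757 with an estimated correlation). Glycolysis genes had 9 of 16 higher and 2 lower, the same adjusted over the list alone, and the glucose transporter Slc2a1 lay at 38.9 ± 0.375 and 83.6 ± 1.86 CPM and lactate dehydrogenase Ldha at 463 ± 29.9 and 833 ± 12.5. The median was 0.36 (camera adjusted p = 0.0279, and adjusted p = 0.233 with an estimated correlation). Fusion and osteoclast genes had 7 of 10 higher and 3 lower, the same adjusted over the list alone, with the fusion protein Ocstamp at 1.04 ± 0.342 and 86.0 ± 2.15 CPM and integrin Itgb3 at 20.0 ± 1.51 and 130 ± 11.1. The median was 1.59 (camera adjusted p = 0.0279, and adjusted p = 0.137 with an estimated correlation).

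Several groups fell in wild type with IL-4. Of 20 interferon-stimulated genes 17 were lower and none higher, the same adjusted over the list alone. The median was -2.12 (camera adjusted p = 2.62e-08, and adjusted p = 0.233 with an estimated correlation). Of 11 measured inflammatory genes 6 were lower and 2 higher, the same adjusted over the list alone. The inflammasome sensor Nlrp3 fell from 36.4 ± 3.35 to 6.09 ± 0.928 CPM, whereas the monocyte chemokine Ccl7 rose from 2.09 ± 0.699 to 34.6 ± 2.08. The median was -0.90 (camera adjusted p = 0.0279, and adjusted p = 0.0829 with an estimated correlation). Of 16 macrophage identity genes 9 were lower and 2 higher, 9 and 4 adjusted over the list alone. The transcription factor Maf lay at 275 ± 28.5 and 47.2 ± 2.72 CPM and the lipopolysaccharide co-receptor Cd14 at 438 ± 83.3 and 42.0 ± 4.85. The list median was -0.35 (camera adjusted p = 0.0115, and adjusted p = 0.0757 with an estimated correlation). Of 14 complement and clearance genes 8 were lower and 1 higher, 11 and 2 adjusted over the list alone. Gas6, which bridges dead cells to phagocyte receptors, lay at 368 ± 4.91 and 92.2 ± 0.231 CPM and C1qa at 367 ± 29.95 and 157 ± 16.0. The median was -0.58 (camera adjusted p = 0.000536, and adjusted p = 0.0757 with an estimated correlation).

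Among markers of other cell types, the B cell and the T and NK lists were called in wild type. The B cell list had 2 of 7 members measured, Cd79b, a chain of the B cell receptor, and Ighm, the immunoglobulin mu heavy chain, which fell from 172 ± 8.4 to 50.5 ± 7.74 CPM. Both were lower, also adjusted over the list alone. The median was -1.70 (camera adjusted p = 0.0115, and adjusted p = 0.0829 with an estimated correlation). The T and NK list had 2 of 10 measured, the NK receptor Klrb1c and the co-receptor Cd4, which fell from 21.6 ± 7.71 to 1.93 ± 0.157 CPM. Both T and NK members were lower, also adjusted over the list alone. The median was -2.31 (camera adjusted p = 0.0321, and adjusted p = 0.105 with an estimated correlation). None of 7 erythroid genes passed the low-count filter.

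The other 11 lists were not called in wild type with camera. IL-4 and STAT6 signalling had 8 of 17 higher and 6 lower, with the feedback inhibitors Cish and Socs1 rising from 1.02 ± 0.170 to 38.7 ± 4.74 and from 0.745 ± 0.318 to 22.1 ± 0.913 CPM (median -0.09 but mean 1.11 and an upward test, adjusted p = 0.231). MHC class II genes had 5 of 12 higher and 3 lower (adjusted p = 0.388), and H2-DMa, which loads peptides, rose from 93.5 ± 8.12 to 178 ± 20.0 CPM. The EGR family had 3 of 5 higher and 1 lower (adjusted p = 0.530), cell cycle genes 2 of 21 and 10 (adjusted p = 0.0507, and 0.0472 with RLE factors), cofactors 2 of 13 and 1 (adjusted p = 0.868) and immediate-early genes 6 of 11 and 4 (adjusted p = 0.202). Neutrophil markers had 2 of 10 higher and 5 lower (median -0.81, mean 0.18 and a downward test, adjusted p = 0.178), and eosinophil markers 1 of 4 and 1 (median -0.09, mean 0.21 and a downward test, adjusted p = 0.796). Mast cell markers had none of 2 called (adjusted p = 0.312), dendritic cell markers 1 of 5 higher and 2 lower (adjusted p = 0.245) and fibroblast markers 1 of 3 higher (median 0.03, and -0.04 with library totals alone; adjusted p = 0.565).

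**Figure D2:**
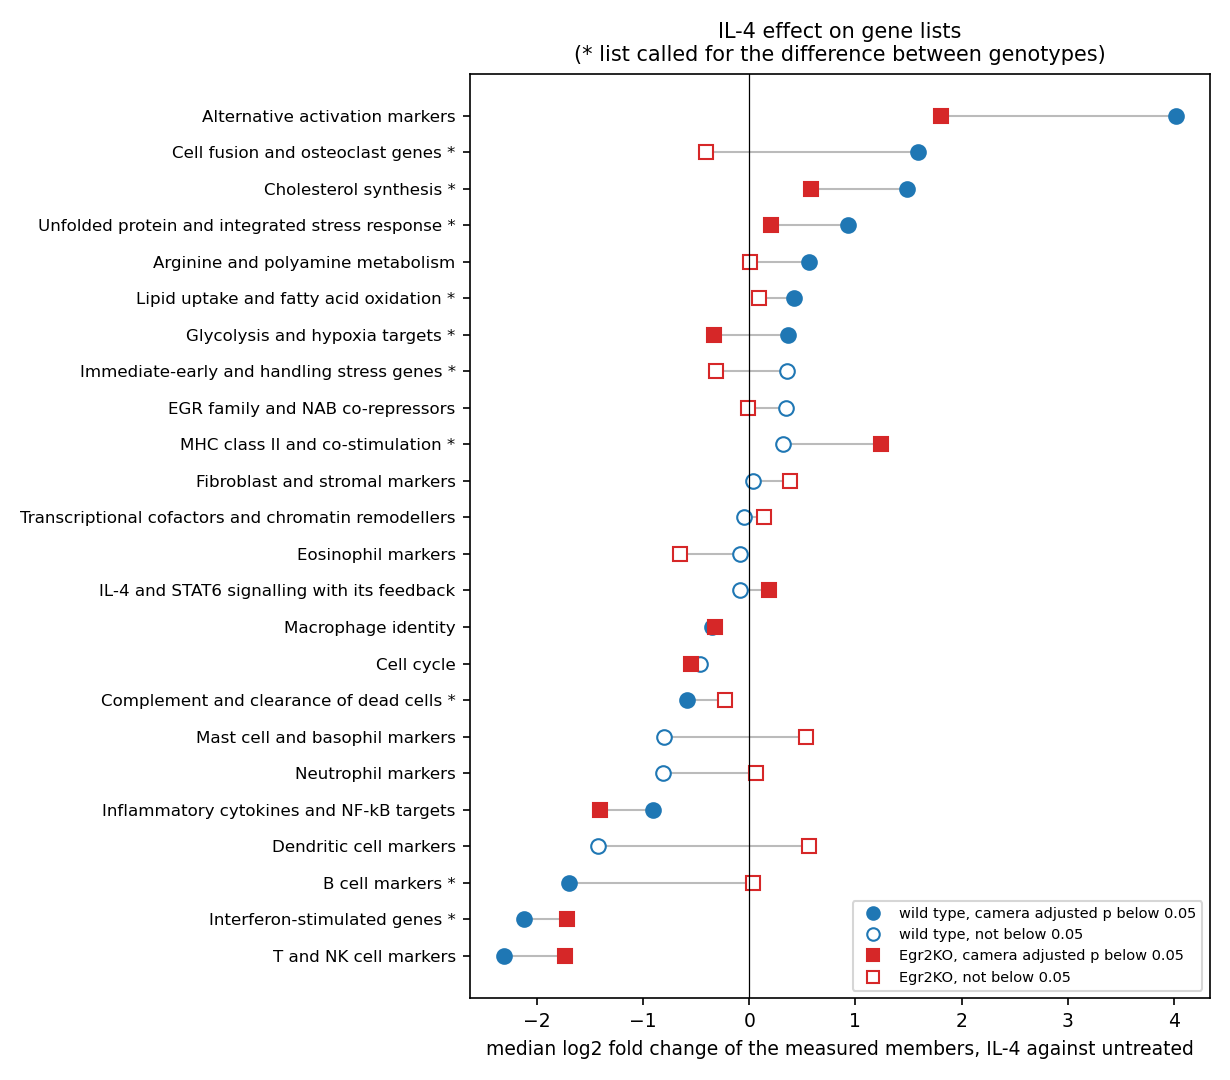
Median log2 fold change of the measured members of 24 gene lists with IL-4 against untreated (horizontal axis, log2), in wild type (blue circles) and Egr2KO (red squares); filled symbols are lists called by camera at the preset correlation, and an asterisk marks lists called for the difference between genotypes. Alternative activation markers lay at 4.02 in wild type and 1.80 in Egr2KO, and cholesterol synthesis genes at 1.49 and 0.58.

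The IL-4 effect in Egr2KO macrophages was the second comparison. Retnla went from 6.37 ± 9.95 to 914 ± 273 CPM, Arg1 from 0.180 ± 0.162 to 27.3 ± 5.53 and Rnase2a from 1.05 ± 1.34 to 742 ± 59.0. All were called higher. Aifm3, of the apoptosis-inducing factor family, the WD-repeat gene Wdr86 and the sodium channel gene Scn9a went from 0 reads to 20.3 ± 2.74, 7.2 ± 1.93 and 5.36 ± 0.473 CPM, at least 498-fold, 177-fold and 132-fold higher. Cldn11 and the homeobox gene Msx3 rose from 1 read each to 35.6 ± 3.30 and 19.5 ± 3.88 CPM, ratios of 2633 (95% counting interval 472 to 104040) and 1439 (258 to 56882). Scn3a rose from 0.116 ± 0.0922 to 106 ± 2.74 CPM. Cx3cr1 fell from 14.9 ± 2.93 to 0.288 ± 0.0333 CPM. Cmah, which hydroxylates sialic acid, fell from 6.33 ± 0.907 to 0.455 ± 0.0553, Siglece from 8.64 ± 0.292 to 0.777 ± 0.273 and the collagen IV chain Col4a2 from 5.12 ± 1.25 to 0.470 ± 0.140. Pcp4l1 fell from 106 ± 8.14 to 9.97 ± 1.83 CPM and Cxcl10 from 11.2 ± 4.03 to 1.08 ± 0.273. Without untreated Egr2KO replicate 1 the log2 change of Cldn11 went from 10.91 to 12.82. Without replicate 3 that of Msx3 went from 10.04 to 11.93, of Arg1 from 7.14 to 8.23, of Rnase2a from 9.37 to 11.35, of Scn3a from 9.71 to 10.58 and of Retnla from 7.11 to 10.50.

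In Egr2KO 1598 genes were higher and 2228 lower with IL-4 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 501 and 647 changed at least 2-fold. The log2 change of Retnla was 7.11 (SE 1.12, adjusted p = 0.00197), that of Scn3a 9.71 (SE 0.28, adjusted p = 6.11e-12) and that of Cx3cr1 -5.67 (SE 0.37, adjusted p = 9.98e-08). Without untreated Egr2KO replicate 3, which held 487 of the group's 516 Retnla reads, they were 10.50 for Retnla (adjusted p = 2.51e-05; range over 16 alternatives 5.23e-07 to 0.0399) and 10.58 for Scn3a. Leaving 1 library out gave 3016 to 3663 genes, the latter without untreated replicate 3.

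Alternative activation markers rose in Egr2KO for 17 of 24 members, with 1 lower, and for 19 with 1 lower adjusted over the list alone. Mgl2 rose from 21.2 ± 3.09 to 720 ± 185 CPM, Mrc1 from 766 ± 47.2 to 2626 ± 15.7 and Chil3 from 37.0 ± 14.3 to 112 ± 47.3. The Chil3 call (edgeR adjusted p = 0.0157) was lost without untreated Egr2KO replicate 2 (adjusted p = 0.0571) and when only these 2 groups were fitted (adjusted p = 0.0824), and ran from 5.40e-06 over the 17 alternatives. Tgm2, a transglutaminase, fell from 37.4 ± 11.8 to 13 ± 4.39 CPM. Pparg lay at 39.9 ± 5.56 and 38.9 ± 4.53 CPM and was not called (log2 -0.03, edgeR adjusted p = 0.876). Ccl22 lay at 0.218 ± 0.0318 and 0.577 ± 0.228 CPM and was not called (adjusted p = 0.0759), but was without IL-4-treated Egr2KO replicate 3 (adjusted p = 0.0374) and with the replicate block within each genotype (adjusted p = 0.0127). Ccl22 was also called with DESeq2, no filter and limma-trend with 0.1 added (adjusted p = 0.0260, 0.0353 and 0.0217). In 11 of 16 alternatives it was not (adjusted p from 0.0127 to 0.233). The list's median was 1.80 (camera adjusted p = 5.60e-14, and adjusted p = 0.0239 with an estimated correlation), the only list call of this comparison that stood with an estimated correlation.

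Cholesterol synthesis genes rose in Egr2KO for 17 of 20, 18 adjusted over the list alone, and fell for 0, with Hmgcs1 at 49.4 ± 3.93 and 83.1 ± 5.62 CPM and Mvd at 13.1 ± 1.14 and 35.1 ± 1.54. The median was 0.58 (camera adjusted p = 6.73e-10, and adjusted p = 0.180 with an estimated correlation). MHC class II and co-stimulation genes rose for 10 of 12 with none lower, and 2 lower adjusted over the list alone. The co-stimulatory ligand Cd86 rose from 14.2 ± 3.25 to 62.0 ± 7.25 CPM, the receptor Cd40 from 11.8 ± 1.97 to 41.0 ± 5.50 and H2-DMa from 55.7 ± 13.8 to 134 ± 20.2. The median was 1.24 (camera adjusted p = 6.53e-06, and adjusted p = 0.236 with an estimated correlation). IL-4 and STAT6 signalling had 7 of 17 higher and 3 lower, 8 and 5 adjusted over the list alone, with Cish at 1.47 ± 0.341 and 39.7 ± 1.38 CPM and Socs1 at 0.749 ± 0.207 and 27.1 ± 2.61. The median was 0.19 (camera adjusted p = 0.0147, and adjusted p = 0.236 with an estimated correlation). The unfolded protein list had 3 of 14 higher and none lower, the same adjusted over the list alone, with Pdia4 at 71.4 ± 5.14 and 169 ± 9.28 CPM. The median was 0.21 (camera adjusted p = 0.00835, and adjusted p = 0.180 with an estimated correlation).

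Cell cycle genes fell in Egr2KO for 15 of 21, 19 adjusted over the list alone, and rose for 0. The replication clamp Pcna fell from 358 ± 12.5 to 208 ± 5.22 CPM and the helicase subunit Mcm6 from 104 ± 1.65 to 62.9 ± 4.81. The median was -0.55 (camera adjusted p = 1.55e-07, and adjusted p = 0.236 with an estimated correlation). Interferon-stimulated genes had 16 of 20 lower and 2 higher, the same adjusted over the list alone, with the antiviral gene Rsad2 at 30.5 ± 8.65 and 4.31 ± 1.40 CPM. The list median was -1.71 (camera adjusted p = 1.55e-07, and adjusted p = 0.317 with an estimated correlation). Glycolysis genes had 7 of 16 lower, 8 adjusted over the list alone, and none higher. Pyruvate kinase Pkm lay at 1663 ± 145 and 1047 ± 36.1 CPM and Pdk1, which inhibits pyruvate dehydrogenase, at 42.2 ± 2.51 and 17.7 ± 0.833. The median was -0.33 (camera adjusted p = 0.000348, and adjusted p = 0.139 with an estimated correlation). Inflammatory genes had 7 of 11 lower and 2 higher, the same adjusted over the list alone. The cytokine Tnf fell from 11.9 ± 1.41 to 2.15 ± 0.295 CPM and Nlrp3 from 51.8 ± 6.71 to 17.0 ± 0.965, and Ccl7 rose from 1.19 ± 0.756 to 52.9 ± 11.3, a log2 change of 5.47, or 6.10 without untreated replicate 2. The median was -1.40 (camera adjusted p = 0.00696, and adjusted p = 0.125 with an estimated correlation). Macrophage identity genes had 8 of 16 lower and 2 higher, 8 and 3 adjusted over the list alone, with Cd14 at 477 ± 73.0 and 80.9 ± 4.06 CPM. The median was -0.32 (camera adjusted p = 0.00835, and adjusted p = 0.125 with an estimated correlation). The T and NK list had its 2 measured members lower, Cd4 and Klrb1c, the latter from 15 to 2 reads over 3 libraries. The median was -1.74 (camera adjusted p = 0.0452, and adjusted p = 0.180 with an estimated correlation).

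The other 13 lists were not called in Egr2KO with camera, at adjusted p from 0.137 to 0.951. Lipid genes had 2 of 17 higher and 5 lower (adjusted p = 0.839), among them the lipase Lpl, which fell from 4541 ± 385 to 1597 ± 169 CPM. Fusion genes had 2 of 10 higher and 3 lower (adjusted p = 0.685), with Itgb3 rising from 24.3 ± 4.06 to 299 ± 18.5 CPM and the fusion protein Dcstamp falling from 3.49 ± 0.998 to 0.472 ± 0.171. The complement component C3 rose from 124 ± 21.2 to 494 ± 119 CPM, within a list of 2 higher and 7 lower of 14 (adjusted p = 0.168), and the immediate-early gene Fos fell from 132 ± 11.1 to 37.3 ± 3.89, within a list of 4 higher and 6 lower of 11 (adjusted p = 0.327). The EGR family had a median of -0.01, a mean of 0.46 and an upward test (adjusted p = 0.685).

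What the loss of Egr2 changes without IL-4 was the third comparison. The extracellular protease Mmp12 (macrophage elastase) lay at 945 ± 250 CPM in wild type and 28.2 ± 12.1 in Egr2KO, the integrin Itgax (CD11c) at 127 ± 23.8 and 5.20 ± 6.01. Coagulation factor F7 lay at 14.6 ± 2.34 and 0.640 ± 0.346, the proton pump subunit Atp6v0d2 at 171 ± 50.6 and 9.58 ± 4.98 and the integrin Itgad at 14.1 ± 2.78 and 1.04 ± 0.766. In the other direction, the matrix protein Thbs1 lay at 14.8 ± 5.10 and 56.9 ± 18.4 CPM, Col4a2 at 1.68 ± 0.443 and 5.12 ± 1.25, the Notch ligand Jag2 at 4.40 ± 0.546 and 12.2 ± 1.71 and the pentraxin Nptx1 at 8.51 ± 1.5 and 23.6 ± 3.85. The cytokine Il1b lay at 2.01 ± 0.269 and 5.34 ± 2.56 CPM and the scavenger receptor Marco at 3.15 ± 0.768 and 7.61 ± 1.15. Without untreated Egr2KO replicate 3 the log2 change of Itgad went from -3.68 to -4.51 and that of Itgax from -4.57 to -6.20.

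With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 112 genes were higher and 501 lower in untreated Egr2KO, 27 and 173 of them by at least 2-fold. Log2 changes were -5.06 (SE 0.37, adjusted p = 4.91e-05) for Mmp12, -4.57 (SE 0.64, adjusted p = 0.00487) for Itgax and 1.98 (SE 0.31, adjusted p = 0.00565) for Thbs1. The count was 362 when only these 2 groups were fitted, where Itgax (adjusted p = 0.142), Il1b (adjusted p = 0.0589), Pparg (adjusted p = 0.154) and Hmgcs1 (adjusted p = 0.0575) lost their calls. It was 629 without untreated Egr2KO replicate 3. Over 16 alternatives each, the adjusted p ran from 4.05e-09 to 0.142 for Itgax, 0.000587 to 0.0919 for Il1b, 0.00192 to 0.154 for Pparg, 0.000122 to 0.0575 for Hmgcs1 and 0.00248 to 0.194 for Marco. The Marco call (adjusted p = 0.0348) was lost without each of the 6 libraries, at adjusted p of 0.194, 0.0941 and 0.0533 without wild-type replicates 1, 2 and 3 and 0.0993, 0.107 and 0.0564 without Egr2KO replicates 1, 2 and 3. The Il1b call (adjusted p = 0.0117) was lost without wild-type replicate 1 (adjusted p = 0.0919). The lowest count with a library left out was 412, without untreated Egr2KO replicate 1.

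Fusion and osteoclast genes were lower in untreated Egr2KO for 4 of 10 members and higher for 0, and 8 and 1 adjusted over the list alone. Dcstamp lay at 32.2 ± 4.65 CPM in wild type and 3.49 ± 0.998 in Egr2KO. This list had a median of -1.07 (camera adjusted p = 1.89e-09, and adjusted p = 0.0129 with an estimated correlation), the only list call of this comparison that stood with an estimated correlation. Cholesterol genes were lower for 3 of 20, 14 adjusted over the list alone, with Hmgcs1 at 67.7 ± 5.76 and 49.4 ± 3.93 CPM. The median was -0.30 (camera adjusted p = 1.89e-09, and adjusted p = 0.386 with an estimated correlation). Lipid genes were lower for 3 of 17, 7 adjusted over the list alone. The fatty acid binding protein Fabp4 lay at 32.5 ± 7.23 and 10.5 ± 3.65 CPM and Plin2 at 900.2 ± 25.2 and 674 ± 7.99. The median was -0.19 (camera adjusted p = 5.40e-07, and adjusted p = 0.0648 with an estimated correlation). MHC class II genes were lower for 1 of 12, and lower for 8 and higher for 2 adjusted over the list alone. The median was -0.70 (camera adjusted p = 0.000328, and adjusted p = 0.409 with an estimated correlation). The called member, H2-DMa, lay at 93.5 ± 8.12 and 55.7 ± 13.8 CPM (edgeR adjusted p = 0.0198) and lost its call without wild-type replicate 2 (adjusted p = 0.0889) or 3 (adjusted p = 0.0717) or Egr2KO replicate 1 (adjusted p = 0.108), with a range over 16 alternatives from 0.00015 to 0.108. Glycolysis genes were lower for 2 of 16, 3 adjusted over the list alone, with Slc2a1 at 38.9 ± 0.375 and 25.2 ± 4.30 CPM and Pdk1 at 58.7 ± 2.12 and 42.2 ± 2.51. The median was -0.09 (camera adjusted p = 0.0364, and adjusted p = 0.409 with an estimated correlation).

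Alternative activation markers were not called as a list without IL-4 (camera adjusted p = 0.587), with 3 of 24 lower, the same adjusted over the list alone, and a median of 0.10 and mean of 0.06 against a downward test. The called members were Clec7a, the beta-glucan receptor dectin-1, at 156 ± 36.8 CPM in wild type and 33.9 ± 3.27 in Egr2KO, the kinase Matk at 37.5 ± 4.21 and 15.9 ± 2.38, and Pparg at 53.4 ± 4.37 and 39.9 ± 5.56. The Pparg call (edgeR adjusted p = 0.0459) was lost without wild-type replicate 1 (adjusted p = 0.138) or 2 (adjusted p = 0.151), without Egr2KO replicate 1 (adjusted p = 0.0629) or 2 (adjusted p = 0.124), and with library totals alone (adjusted p = 0.109). Nab2, a co-repressor that binds EGR proteins, was lower at 26.7 ± 2.47 against 58.4 ± 1.42 CPM, within an EGR list of 2 lower and 1 higher of 5 (median 0.02, mean -1.13, camera adjusted p = 0.130). The other lower member was Egr2 itself, the targeted gene, at -6.03. It pulls the list mean down and is no evidence on the rest of the family. Mfge8, which bridges apoptotic cells to phagocytes, was lower at 20.7 ± 4.22 against 141 ± 43.1 CPM. Properdin, Cfp, was higher at 521 ± 41.2 against 364 ± 4.05, within a complement list with a median of 0.03 and mean of -0.10 (camera adjusted p = 0.943). The cathepsin Ctss was lower at 2158 ± 152 against 3298 ± 172 CPM and the stress factor Atf3 at 248 ± 21.2 against 398 ± 9.78. Atf3 went against its immediate-early list, which had 2 of 11 higher and 1 lower (median 0.25, camera adjusted p = 0.483). Medians within 0.05 of 0 changed sign with library totals alone for arginine (main -0.01, totals 0.04) and, near 0 throughout, for IL-4 and STAT6 signalling, macrophage identity, cofactor and fibroblast genes; none of these lists was called with either scaling.

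Egr2KO against wild type with IL-4 was the fourth comparison and had the most called genes. Ocstamp lay at 86.0 ± 2.15 CPM in wild type and 0.0766 ± 0.0709 in Egr2KO, Dcstamp at 85.7 ± 8.46 and 0.472 ± 0.171 and Itgax at 1135 ± 87.9 and 3.63 ± 0.160. Mmp12 lay at 2959 ± 226.9 and 21.1 ± 6.85 and the transcription factor Myrf at 15.3 ± 1.94 and 0.0921 ± 0.0934. Eef1a2, an elongation factor paralog, lay at 9.88 ± 1.38 CPM in wild type and had 0 reads in Egr2KO, at least 219-fold lower. In the other direction Adgre4 lay at 0.497 ± 0.212 and 38.3 ± 6.09 CPM, Aifm3 at 0.718 ± 0.302 and 20.3 ± 2.74. The growth factor gene Nrg1 lay at 0.408 ± 0.320 and 15.2 ± 2.53 and Pgf at 0.354 ± 0.334 and 10.1 ± 6.69, Wdr86 at 0.168 ± 0.114 and 7.2 ± 1.93, and Kmo, an enzyme of tryptophan breakdown, at 1.13 ± 0.348 and 25.4 ± 4.80. With 1 IL-4-treated library left out, the log2 change of Wdr86 went from 5.32 to 5.96 (wild-type replicate 2) and that of Pgf from 4.82 to 5.94 (wild-type replicate 3) or 4.13 (Egr2KO replicate 2). Without Egr2KO replicate 1 that of Myrf went from -7.32 to -8.27 and that of Ocstamp from -10.06 to -10.76.

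With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 4321 genes were higher and 4582 lower in Egr2KO with IL-4, 1358 and 1319 of them by at least 2-fold. With library totals alone the counts were 5989 and 3589, a share of 62.5% higher against 48.5%, and the median over all genes shifted by 0.123 on the log2 scale. The log2 change was -10.06 (SE 0.36, adjusted p = 2.11e-10) for Ocstamp, -7.13 (SE 0.41, adjusted p = 3.92e-07) for Mmp12 and 6.21 (SE 0.43, adjusted p = 7.69e-07) for Adgre4.

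Alternative activation markers divided with IL-4, with 7 of 24 higher and 14 lower in Egr2KO, 8 and 14 adjusted over the list alone, and no call as a list (median -1.23, camera adjusted p = 0.186). Lower were Ccl22 at 0.577 ± 0.228 against 17.5 ± 6.95 CPM, Chil3 at 112 ± 47.3 against 643 ± 132, Clec7a at 82.7 ± 11 against 503 ± 15.8, Pparg at 38.9 ± 4.53 against 133 ± 8.88 and Arg1 at 27.3 ± 5.53 against 51.5 ± 8.59 CPM. Higher were the lectins Mgl2 at 720 ± 185 against 194 ± 42.7 CPM and Clec10a at 562 ± 42.9 against 140 ± 30.3, and Mrc1 at 2626 ± 15.7 against 1178 ± 29.2. These directions were the same under each scaling. Retnla at 914 ± 273 against 2522 ± 392 CPM was not called (edgeR log2 -1.47, adjusted p = 0.189) except when only these 2 groups were fitted (adjusted p = 0.00812; range over 15 alternatives to 0.342). Neither was Rnase2a at 742 ± 59.0 against 271 ± 149 (log2 1.45, adjusted p = 0.0698), which was called with library totals alone (adjusted p = 0.0485), the replicate block (adjusted p = 0.0427) and limma-trend with 1 added (adjusted p = 0.00813), and not in 13 of 16 alternatives (adjusted p from 0.00813 to 0.280).

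Metabolic groups were lower in Egr2KO with IL-4, and none of these list calls stood with an estimated correlation. Cholesterol genes were lower for 19 of 20, the same adjusted over the list alone, with Hmgcs1 at 83.1 ± 5.62 against 247 ± 16.4 CPM and the sterol demethylase Cyp51 at 53.9 ± 4.95 against 218 ± 16.9. The list median was -1.24 (camera adjusted p = 8.84e-10, and adjusted p = 0.244 with an estimated correlation). Lipid genes were lower for 13 of 17, the same adjusted over the list alone, with Lpl at 1597 ± 169 against 6662 ± 465 CPM and the fatty acid transporter Cd36 at 812 ± 110 against 3822 ± 254. The median was -0.51 (camera adjusted p = 9.37e-06, and adjusted p = 0.132 with an estimated correlation). Glycolysis genes were lower for 12 of 16 and higher for 1, the same adjusted over the list alone, with Slc2a1 at 23.6 ± 1.07 against 83.6 ± 1.86 CPM and Ldha at 335 ± 21.8 against 833 ± 12.5. The median was -0.86 (camera adjusted p = 3.20e-05, and adjusted p = 0.132 with an estimated correlation). The unfolded protein list had 9 of 14 lower and 2 higher, the same adjusted over the list alone, with Hspa5 at 466 ± 40.0 against 1122 ± 54.2 CPM and Sdf2l1, an endoplasmic reticulum protein, at 47.4 ± 4.15 against 156 ± 14.2. The median was -0.56 (camera adjusted p = 0.0203, and adjusted p = 0.248 with an estimated correlation). Fusion genes had 7 of 10 lower and 2 higher, the same adjusted over the list alone. The median was -2.74 (camera adjusted p = 0.00633, and adjusted p = 0.174 with an estimated correlation). Interferon-stimulated genes had 8 of 20 higher and 1 lower, the same adjusted over the list alone, with the RNA sensor Ddx58 at 48.2 ± 7.08 against 22.0 ± 0.632 CPM and the interferon-response protease Usp18 at 3.36 ± 1.10 against 11.6 ± 1.03. The median was 0.59 (camera adjusted p = 0.0203, adjusted p = 0.676 with an estimated correlation and 0.0709 with library totals alone). Both measured B cell markers, Cd79b and Ighm, were higher, also adjusted over the list alone, with Ighm at 247 ± 6.57 against 50.5 ± 7.74 CPM. The median was 2.07 (camera adjusted p = 0.0203, and adjusted p = 0.198 with an estimated correlation).

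Among lists not called with IL-4 (camera adjusted p from 0.0696 to 0.917), single genes differed by edgeR's test. Maf lay at 244 ± 5.37 in Egr2KO against 47.2 ± 2.72 CPM in wild type and the F4/80 gene Adgre1 at 3095 ± 210 against 1254 ± 43.9, in a macrophage identity list of 7 higher and 6 lower of 16 (median -0.09 and mean 0.21, median 0.04 with library totals alone). Gas6 lay at 447 ± 56.9 against 92.2 ± 0.231 CPM and C3 at 494 ± 119 against 135 ± 15.8, in a complement list of 8 higher and 3 lower of 14 (camera adjusted p = 0.0696). Cd86 lay at 62.0 ± 7.25 against 5.11 ± 0.960 CPM, Cd40 at 41.0 ± 5.50 against 11.2 ± 0.647 and Cd4 at 19.1 ± 5.11 against 1.93 ± 0.157. Myc lay at 12.2 ± 2.13 against 46.6 ± 1.66 CPM and the feedback inhibitor Socs2 at 0.816 ± 0.151 against 4.49 ± 0.802, in an IL-4 and STAT6 list with a median of 0.03, a mean of -0.22 and a downward test. Nab2 lay at 19.7 ± 1.43 against 74.3 ± 1.36 CPM, spermidine synthase Srm at 8.77 ± 0.939 against 28.2 ± 1.53 and Pcna at 208 ± 5.22 against 722 ± 70.8. Dendritic cell markers had 3 of 5 higher and none lower (median 2.61, camera adjusted p = 0.186). The cell cycle list had 6 of 21 higher and 8 lower (median -0.06, and 0.07 with library totals alone), and the EGR list a median of 0.37 with a mean of -1.18.

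Whether the IL-4 effect itself differed between genotypes was the fifth comparison, tested as a difference of differences. Ocstamp rose with IL-4 in wild type from 1.04 ± 0.342 to 86.0 ± 2.15 CPM and lay at 0.411 ± 0.376 and 0.0766 ± 0.0709 CPM in Egr2KO, a difference of -8.72 on the log2 scale. Without untreated Egr2KO replicate 3 it was -7.58, and without IL-4-treated Egr2KO replicate 1 it was -9.42. Eef1a2, the acyltransferase gene Awat1, the integrin Itgb8, Myrf and the immunoglobulin-superfamily gene Igsf3 lay at 9.88 ± 1.38, 6.93 ± 1.75, 5.43 ± 1.01, 15.3 ± 1.94 and 5.57 ± 2.05 CPM in wild type with IL-4 and at most 0.319 CPM, the mean of Igsf3, in Egr2KO with IL-4. Adgre4 fell with IL-4 in wild type and lay at 48.4 ± 17.7 and 38.3 ± 6.09 CPM in Egr2KO (difference 5.01). The chemokine receptor Cxcr3 lay at 4.55 ± 0.0918 and 0.336 ± 0.0754 CPM in wild type and 5.06 ± 0.547 and 5.99 ± 0.453 in Egr2KO (difference 3.98). The apolipoprotein L genes Apol7c, Apol7b and Apol7e, which have close copies, reached 303 ± 102, 16.1 ± 6.28 and 19.1 ± 6.91 CPM in Egr2KO with IL-4 against 27.3 ± 4.64, 1.38 ± 0.328 and 1.71 ± 0.361 in wild type. The short-chain fatty acid receptor Ffar2 reached 5.61 ± 1.90 against 0.339 ± 0.0926 CPM.

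With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, the IL-4 effect was higher in Egr2KO for 2000 genes and lower for 2404, of which 760 and 707 differed at least 2-fold. With library totals alone 2463 were higher and 1961 lower, a share of 55.7% higher against 45.4%. Of 824 genes raised at least 2-fold in wild type, 441 (53.5%) had a called lower effect in Egr2KO, 34 of them with a called fall there, and 63 (7.65%) a higher one. The median log2 change of the 824 was 1.55 in wild type and 0.46 in Egr2KO. Of 1172 genes lowered at least 2-fold in wild type, 567 (48.4%) had a called higher effect in Egr2KO, 31 of them with a called rise there, and 12 (1.02%) a lower one, with medians of -1.45 and -0.59. Choosing genes by their wild-type response favours a smaller response in Egr2KO, so genes chosen in Egr2KO were also counted. Of 501 genes raised at least 2-fold in Egr2KO, 246 (49.1%) had a called higher effect there than in wild type and 32 (6.39%) a lower one, with medians of 1.00 in wild type and 1.82 in Egr2KO. Of 647 lowered at least 2-fold in Egr2KO, 242 (37.4%) had a called lower effect there and 51 (7.88%) a higher one, with medians of -0.96 and -1.46. Simulated counts with the same response in both genotypes gave 0 called differences, so they cannot show how much choosing genes by 1 genotype adds. The count of called differences was 3904 without untreated Egr2KO replicate 3, where Awat1 (adjusted p = 0.135 against 0.0012) and Itgb8 (adjusted p = 0.246 against 0.00185) lost their calls. Apol7b (adjusted p = 0.0217) lost its call without that library or untreated wild-type replicate 2 or 3 (adjusted p = 0.0616, 0.0606 and 0.0968). Over 22 alternatives the adjusted p ran from 3.37e-07 to 0.135 for Awat1, 6.17e-07 to 0.246 for Itgb8 and 7.33e-06 to 0.0968 for Apol7b.

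**Figure D3:**
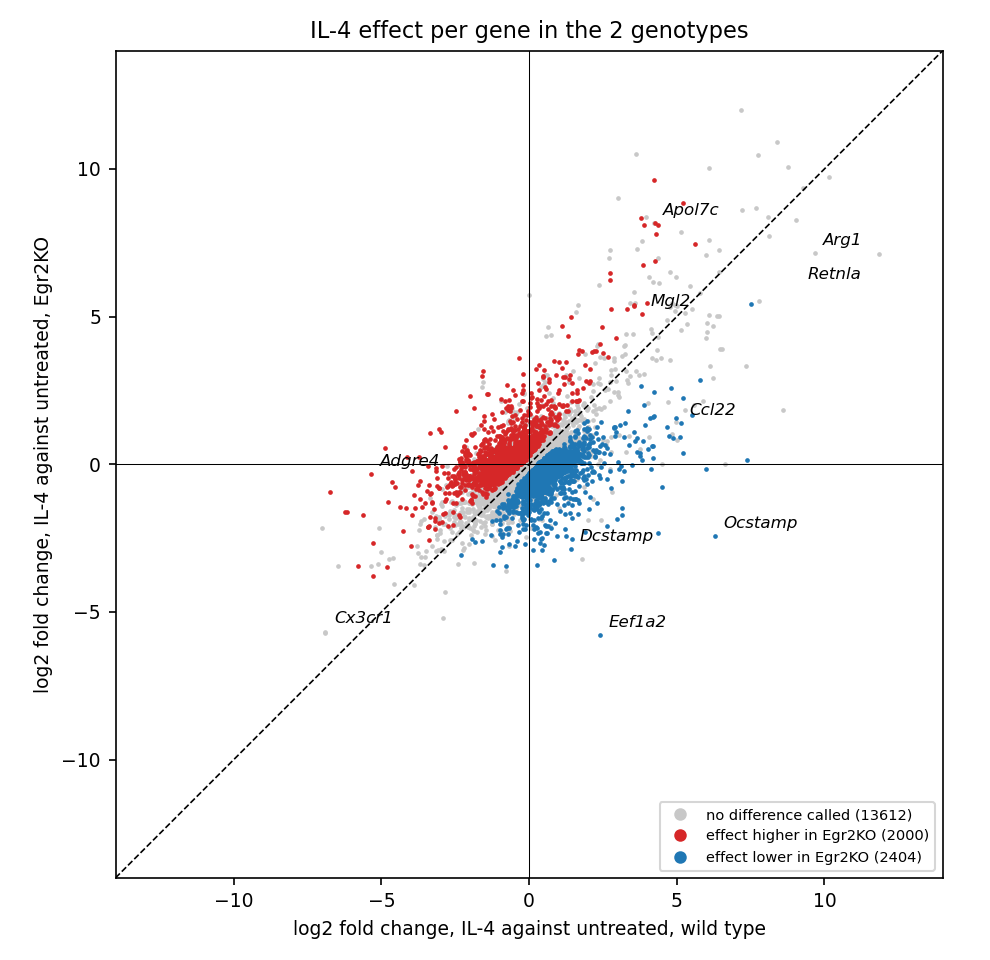
Log2 fold change with IL-4 against untreated in wild type (horizontal axis) and Egr2KO (vertical axis), each point being 1 of 18016 genes; red points had a called higher effect in Egr2KO, blue points a called lower effect, grey points no called difference, and the dashed line marks equal effects. Ocstamp lies below the line at 6.29 in wild type and Adgre4 above it at -5.35 in wild type.

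Among alternative activation markers 6 of 24 had a higher and 6 a lower IL-4 effect in Egr2KO, 6 and 9 adjusted over the list alone, and the list was not called (median -1.0, camera adjusted p = 0.187). Lower effects were called for Ccl22 (log2 difference -3.74, SE 0.72), Chil3 (-2.61, SE 0.54) and Pparg (-1.35, SE 0.16), with edgeR adjusted p of 0.00146, 0.00738 and 1.56e-05. Higher effects were called for Mgl2 (1.25, SE 0.31), Mrc1 (1.02, SE 0.12) and Il4ra (0.76, SE 0.15), with edgeR adjusted p of 0.0129, 2.53e-05 and 0.00163; for Mgl2 the adjusted p was 0.0508 with the replicate block within each genotype and from 4.65e-05 in the other alternatives. Retnla (-4.72, SE 1.68) and Arg1 (-2.54, SE 0.93) were not called, with edgeR adjusted p of 0.0773 and 0.0633. Retnla was called without untreated Egr2KO replicate 1 (adjusted p = 0.0496) or 2 (adjusted p = 0.0335) and not in 19 of 21 alternatives (to 0.497). Without untreated Egr2KO replicate 3 the Retnla difference was -1.34 (adjusted p = 0.497) and that of Arg1 -1.44 (adjusted p = 0.446). Without untreated wild-type replicate 1 they were -3.65 and -1.48, and without untreated wild-type replicate 3 that of Retnla was -5.68. Arg1 was called without wild-type IL-4 replicate 1 or Egr2KO IL-4 replicate 1 or 3 (adjusted p = 0.0462, 0.0423 and 0.0497). It was also called with DESeq2 (adjusted p = 0.00337), limma-trend (adjusted p = 0.0046 with 1 added and 0.0435 with 0.1 added) and the replicate block within each genotype (adjusted p = 0.0377), and not in 15 of 22 alternatives (to 0.446). Pdcd1lg2, the PD-1 ligand gene PD-L2, rose to 39.3 ± 4.90 CPM in wild type and 38.4 ± 3.78 in Egr2KO, with a difference of 0.08 (SE 0.42, edgeR adjusted p = 0.916).

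Cholesterol synthesis genes had a lower IL-4 effect in Egr2KO for 19 of 20, the same adjusted over the list alone, with Hmgcs1 at -1.11 and Cyp51 at -1.42. The median was -0.96 (camera adjusted p = 2.39e-09, and adjusted p = 0.189 with an estimated correlation). None of the list calls for this difference stood with an estimated correlation. Glycolysis genes had a lower effect for 11 of 16 and a higher one for 1, 12 and 1 adjusted over the list alone, with hexokinase Hk2 at -1.69 and Pgk1 at -1.17. The median was -0.78 (camera adjusted p = 6.12e-06, and adjusted p = 0.091 with an estimated correlation). The unfolded protein list had 8 of 14 lower and 1 higher, 10 and 2 adjusted over the list alone, with Creld2 at -1.34 and Hspa5 at -1.08. The list median was -0.68 (camera adjusted p = 0.000779, and adjusted p = 0.091 with an estimated correlation). Lipid genes had 7 of 17 lower, 10 adjusted over the list alone, with Lpl at -1.79. The median was -0.36 (camera adjusted p = 0.00014, and adjusted p = 0.091 with an estimated correlation). Fusion genes had 5 of 10 lower and 2 higher, 7 and 2 adjusted over the list alone, with Dcstamp at -4.29 and Itgb3 at 0.93. The median was -1.27 (camera adjusted p = 0.0482, adjusted p = 0.235 with an estimated correlation and 0.0523 with RLE factors). Immediate-early genes had 5 of 11 lower, the same adjusted over the list alone, with Fos at -1.59 and Jun at -1.27. The median was -0.19 (camera adjusted p = 0.0146, and adjusted p = 0.091 with an estimated correlation).

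A higher IL-4 effect in Egr2KO was called for some lists. MHC class II genes had 4 of 12 higher and none lower, the same adjusted over the list alone, with Cd86 at 2.94 and Cd40 at 1.55. The median was 0.88 (camera adjusted p = 0.00237, and adjusted p = 0.421 with an estimated correlation). The list median, Egr2KO against wild type, was -0.70 without IL-4 and 0.07 with it. Complement genes had 8 of 14 higher and none lower, 8 and 1 adjusted over the list alone, with Gas6 at 1.97. The median was 0.54 (camera adjusted p = 0.0119, and adjusted p = 0.154 with an estimated correlation). Interferon-stimulated genes had 3 of 20 higher and 1 lower, the same adjusted over the list alone. The median was 0.48 (camera adjusted p = 0.0401, adjusted p = 0.631 with an estimated correlation and 0.0832 with library totals alone). Both measured B cell markers, Cd79b and Ighm, had a higher effect, also adjusted over the list alone, with Ighm at 1.87. The median was 1.74 (camera adjusted p = 0.00638, and adjusted p = 0.091 with an estimated correlation). Of lists not called, arginine genes had 5 of 13 lower and 1 higher (median -0.89, camera adjusted p = 0.0732, and 0.0481 with library totals alone), and dendritic cell markers 2 of 5 higher (median 1.99, adjusted p = 0.0881). Neutrophil markers had none of 10 called (median 0.76, adjusted p = 0.141). The macrophage identity list, not called either, had 6 of 16 higher and 4 lower, with Maf at 2.14, and the inflammatory list 4 of 11 higher and 2 lower, with Tnf at -1.57. IL-4 and STAT6 signalling had a median of -0.03 and a mean of -0.21 with an upward test (median 0.05 with library totals alone), and the EGR list a median of 0.25 and a mean of -0.05.

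Across the 18016 genes, log2 changes with IL-4 in wild type and Egr2KO had a Pearson correlation of 0.581 and a Spearman correlation of 0.339, and those of Egr2KO against wild type without and with IL-4 0.647 and 0.586; genes are not independent replicates. These pairs of comparisons share no library. With IL-4, 812 genes were called higher and 1259 lower in both genotypes, against 332 and 455 for independent lists of these lengths. Another 256 were higher in wild type and lower in Egr2KO against 464, and 159 lower and higher against 326. Of the 112 genes higher in untreated Egr2KO, 90.2% were also higher with IL-4, where independent lists would share 26.9 genes. Of the 501 lower, 97.4% (488) were also lower, where independent lists would share 127. Mmp12, Itgax and Dcstamp are among the latter.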

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

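Apart from the test of genes near Egr2, the tests of explanations and the counts of other splits in this part were chosen after the results were seen. Every result here had a called difference of the IL-4 effect between genotypes. Values are log2 differences, Egr2KO minus wild type. No group of 4 or more samples allowed a test of single samples.

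The IL-4 effect differed for 4404 genes. The median difference was -1.27 for fusion and osteoclast genes, -0.96 for cholesterol synthesis, -0.78 for glycolysis, -0.68 for the unfolded protein response, -0.36 for lipid genes and -0.19 for immediate-early genes. It was 0.48 for interferon-stimulated genes, 0.54 for complement and clearance, 0.88 for MHC class II and 1.74 for the B cell markers. None of these 10 lists was called with an estimated correlation (adjusted p from 0.091 to 0.631). The IL-4 effect was lower in Egr2KO for Ocstamp (-8.72), Eef1a2 (-8.19), Awat1 (-6.13), Itgb8 (-5.27), Myrf (-4.87), Igsf3 (-4.84) and Dcstamp (-4.29). Among alternative activation markers it was lower for Ccl22 (-3.74), Chil3 (-2.61), Tgm2 (-1.94) and Pparg (-1.35). Among metabolic genes it was lower for Lpl (-1.79), Hk2 (-1.69), Cyp51 (-1.42), Slc2a1 (-1.20), Pgk1 (-1.17), Hmgcs1 (-1.11), Pkm (-1.04), Ldha (-1.02), Mvd (-1.01), Plin2 (-0.98) and Pdk1 (-0.84). Further lower effects were those of Fos (-1.59), Tnf (-1.57), Pcna (-1.42), Creld2 (-1.34), Jun (-1.27), Hspa5 (-1.08), Pdia4 (-0.72) and Mcm6 (-0.65). The effect was higher in Egr2KO for Adgre4 (5.01), Apol7e (4.55), Apol7b (4.20), Cxcr3 (3.98), Apol7c (3.90), Ffar2 (3.78), Cd86 (2.94), Cd4 (2.56), Maf (2.14), Gas6 (1.97), Ighm (1.87), Cd40 (1.55), C3 (1.51), Cmah (1.51) and Ccl7 (1.47). Smaller higher effects were those of Siglece (1.32), Mgl2 (1.25), Mrc1 (1.02), Nlrp3 (0.97), Itgb3 (0.93), Cd14 (0.82), Il4ra (0.76) and C1qa (0.73). Awat1, Itgb8 and Apol7b were not called with certain untreated libraries left out, as given above. Values that 1 library moved by over 1.5-fold were -7.58 for Ocstamp, -4.68 for Awat1 and -3.57 for Itgb8 without untreated Egr2KO replicate 3. They were -9.42 for Ocstamp and -5.82 for Myrf without IL-4-treated Egr2KO replicate 1. Without untreated wild-type replicate 1 they were -3.76 for Igsf3, 5.22 for Apol7b and 5.57 for Apol7e, and without untreated wild-type replicate 3 that of Apol7b was 3.59.

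Other splits of the same libraries were counted for each comparison. The 10 splits of 6 libraries into 3 and 3 cannot give a share under 0.05. In each of the 4 comparisons of that size 1 split, the real one, gave as many genes, with 7428 against a highest other count of 0 for IL-4 in wild type, 3826 against 2 for IL-4 in Egr2KO, 613 against 42 for the genotypes without IL-4 and 8903 against 1 with IL-4. For the difference between genotypes, 11 of 100 splits drawn from 200 gave at least the real 4404 genes, with a highest other count of 7912, so this count does not exclude chance. The other 10 kept the IL-4 libraries whole by genotype and regrouped the untreated ones, which points to a structure of the samples, since the IL-4-treated genotypes differ for 8903 genes whichever untreated libraries they are set against. The 80 splits that kept neither treatment whole gave at most 5 genes.

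The first pattern is that untreated Egr2KO replicate 3 held 43 Egr2 reads against 2 and 1 in replicates 1 and 2, and 17.9 CPM of Retnla against 0.857 and 0.409. Untreated cells that kept Egr2 are argued against, because untreated wild type held 1.04 ± 0.97 CPM of Retnla and the excess in replicate 3 was 17.2 CPM. A share of an IL-4-treated Egr2KO culture is argued against too, because 18 genes high only there had a median excess of -0.14% of their level (95% interval -0.204 to 0), where Retnla would need 1.89%. Reads or cells from an IL-4-treated wild-type culture, at about 0.912% (interval 0.586 to 1.24) over 23 genes high only there, 20 of them in excess over replicates 1 and 2, may account for it, since Retnla needs 0.683% and Egr2 0.83%. The 37, 35 and 44 Egr2 reads in the IL-4-treated Egr2KO libraries were 0.966% of the IL-4-treated wild-type level. A share of wild-type reads, or undeleted cells that respond like wild type, would bring each of the same 23 genes to at least that share. Only 2 of them, short of the 3 set as the bound, lay below it. Ocstamp held 5 reads (upper 95% counting bound 11.7) where 54.8 would be needed, and Itgax 240 (upper bound 272) where 723 would. These 2 genes argue against such a share as the whole source of the Egr2 reads. The other genes cannot decide, since Egr2KO cells may express them. A smaller share and reads from exons left in the deleted allele cannot be told apart.

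The second pattern is that 246 genes rose at least 2-fold with IL-4 in Egr2KO and with a called higher effect than in wild type, where 25 of them fell, with a median log2 difference of 1.58. Library scaling is argued against as the whole cause, since 236 of them kept the call under both other scalings. For the Apol7 genes, the summed reads of 5 members differed by 3.88 (SE 0.639, edgeR adjusted p = 0.00192) as well. Reads shared between copies are therefore argued against for the family as a whole. For Apol7b and Apol7e they are not, since Apol7c made up most of the 375 CPM in Egr2KO with IL-4. Dendritic cells in the IL-4-treated Egr2KO cultures remain open: their 5 measured markers had a median log2 change of 0.56 with IL-4 in Egr2KO, 1 of them called higher, of 1.99 for the difference, 2 called higher, and of 2.61 for Egr2KO against wild type with IL-4, 3 called higher and none lower. Camera called the list in none of these, and the least abundant marker held 5 reads in a library, too few to decide. A release of these genes from an effect of EGR2 is the biological candidate that the design names; it was not tested apart from these.

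The third pattern is that some genes differed at least 4-fold between replicate numbers in the same way in untreated and IL-4-treated libraries. In wild type 8 of 11 such genes had the same highest and lowest number in both treatments, against at most 2 under the other 5 of 6 numberings. In Egr2KO 8 of 10 did, against at most 2. The labelled numbering is best 1 time in 6 by chance, so this cannot decide whether numbers are unrelated between treatments. In Egr2KO 5 of the 10 (Gm24270, Mir6236, Gm24187, Gm23935 and Gm15564) moved with Lars2 over the 6 libraries and are not separate evidence. Without them 5 of 5 matched, against at most 1 under another numbering. Atp6v0e2 lay at 0.111 and 0.0594 CPM in wild-type replicate 1 and at 11.7 to 14.4 CPM in the other 4 wild-type libraries. Fggy lay at 0.0902 and 0 CPM in Egr2KO replicate 1, at 19.4 and 11.9 in replicate 2 and at 2.64 and 2.02 in replicate 3. Replicates of 1 number from 1 marrow donor are a candidate that the labels neither state nor exclude and no test here decides. The genes named were chosen after their values were seen.

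Among genes within 20 Mb of Egr2, 23 of 326 (7.06%) were called in untreated Egr2KO against 551 of 15251 (3.61%) elsewhere, an odds ratio of 2.02 (95% interval 1.25 to 3.13; Fisher's exact test, one-sided p = 0.00229). The rate was 1.95 times that elsewhere, short of the 2 times set before the test was run, and the interval does not exclude 2. A comparison added afterwards found that 5.15% of 485 windows across the genome had as high a rate, so linked alleles of another strain and chance clustering cannot be told apart. Of the 23 genes 19 were lower and 4 higher, and 86.5% of tested genes had a position.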

How the results depend on the processing

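Only thinning and the block within each genotype were chosen after the data were seen. Of 3378 values of 192 results on named genes other than Egr2, 3321 kept their direction and side of the threshold, 31 lost the call, 20 gained one and 6 reversed, the 6 all with a library left out; 173 results kept both throughout. All 192 kept both with RLE factors, the stricter filter and the thinned library. Counts of called genes without 1 library ran from 6266 to 7072 for IL-4 in wild type, 3016 to 3663 for IL-4 in Egr2KO, 412 to 638 for the genotypes without IL-4, 7581 to 8072 with IL-4 and 3515 to 4471 for the difference; other alternatives gave 7089 to 7863, 3501 to 4425, 362 to 731, 8437 to 9999 and 4140 to 5049. Only the 362, from fitting the 2 untreated groups alone with fewer samples for the spread, was beyond 1.5 times the main 613. With library totals alone, 3096 genes were higher and 4489 lower with IL-4 in wild type (40.8% higher against 50.5%), and 160 and 423 in untreated Egr2KO (27.4% against 18.3%).

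Egr2 in Egr2KO with IL-4 was called by limma-trend, at 0.95 with 1 added and 2.39 with 0.1 added, and ran from 0.96 to 4.67 with a library left out, called without untreated Egr2KO replicate 3. Its difference between genotypes was called by limma-trend with 1 added (-1.18), reversed with 0.1 added (0.24), and ran from -1.20 to 2.50 with a library left out, reversed without that replicate, which holds 43 of the group's Egr2 reads. Uncalled values near 0 also reversed: Pparg in Egr2KO ran from -0.15 to 0.057 and the Pdcd1lg2 difference from -0.25 to 0.67 with a library left out. The cause of the limma changes was not tested.

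With an estimated correlation the lists called numbered 0, 1, 1, 0 and 0 in the order above, against 13, 11, 5, 7 and 10; fry, which does not compare a list with other genes, called 19, 17, 8, 19 and 15. Uncalled lists reversed direction with fry in Egr2KO with IL-4 for lipid (adjusted p = 0.234), fusion (0.0789) and neutrophil genes (0.985), and for the difference for IL-4 and STAT6 (0.888) and EGR genes (0.858). With the replicate block, complement and T and NK genes without IL-4 reversed (0.974 each), and IL-4 and STAT6 genes for the difference (0.973; 0.996 with the block within genotypes), as did neutrophil genes in Egr2KO with the latter (0.744); the cause was not tested.

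The block within genotypes, the paired fit, gave 4425 genes for IL-4 in Egr2KO and 5049 for the difference, against 3826 and 4404. The replicate block across genotypes gave 7435, 3944, 709, 9009 and 4488 genes. Deviations of same-numbered wild-type libraries correlated at 0.18, 0.02 and 0.39 between treatments, with number 2 not closest to its own; every Egr2KO library was closest to its own number. Under the block the cell cycle list in wild type (adjusted p = 0.0476) and the neutrophil list for the difference (0.0166) were called and the glycolysis list without IL-4 (0.0679) was not. Within genotypes the cell cycle (0.0167) and neutrophil (0.0266) lists were called in wild type and the latter for the difference (0.00296), Tgm2 gained its call in wild type (0.00212) and Arg1 its difference (0.0377), and Mgl2 lost its difference call (0.0508). Rnase2a with IL-4 was called under the block (0.0427); in the Egr2KO comparison, where numbers pair, only Ccl22 changed. Other called named genes kept their calls under both blocks. Depth limits genes near 0 reads in a group, whose fitted changes rest on single reads.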

Other observations

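The test of equal response in this part, and every gene it names, were chosen after the values were seen. Genes that IL-4 moved in opposite directions in the genotypes numbered 256 higher in wild type and lower in Egr2KO, and 159 lower and higher. The matrix metalloproteinase Mmp19 went from 60.1 ± 2.94 to 404 ± 4.85 CPM in wild type and from 46.2 ± 1.43 to 39.5 ± 1.68 CPM in Egr2KO. The proteoglycan Sdc1 (syndecan 1) went from 39.4 ± 2.87 to 55.6 ± 2.16 and from 16.1 ± 1.42 to 2.40 ± 0.523 CPM, the potassium channel Kcnn4 from 146 ± 12.8 to 231 ± 12.8 and from 95.8 ± 9.86 to 22.3 ± 1.40, and the growth factor receptor Fgfr1 from 12.2 ± 1.44 to 35.8 ± 2.90 and from 4.96 ± 1.65 to 2.19 ± 0.324. In the other direction, Spic, a transcription factor of iron-recycling macrophages, went from 6.01 ± 2.46 to 1.53 ± 0.347 CPM in wild type and from 10.9 ± 1.36 to 21.9 ± 1.90 in Egr2KO. The cytokine receptor Lifr went from 21.7 ± 4.39 to 5.93 ± 1.05 and from 27.2 ± 2.58 to 56.9 ± 5.09 CPM, the receptor Cd28 from 57.2 ± 6.12 to 29.5 ± 5.38 and from 72.6 ± 13.4 to 177 ± 52.5, and the coagulation factor gene F13a1 from 39.7 ± 13 to 13.8 ± 1.90 and from 50.2 ± 2.93 to 91.4 ± 18.0. For these 8 genes both IL-4 effects and their difference were called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

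Some genes responded alike in both genotypes. Of 1996 genes changed at least 2-fold by IL-4 in wild type, 40 had a 95% interval of the difference between genotypes within 1.5-fold in either direction, 11 of them risen and 29 fallen. Arap3, a regulator of small GTPases, went from 58.8 to 11.4 CPM in wild type and from 52.7 to 10.7 in Egr2KO (log2 difference 0.07, interval -0.25 to 0.38), and the high-affinity IgG receptor Fcgr1 from 139 to 34.5 and from 126 to 28.5 (-0.14, -0.49 to 0.20). The kinase genes Jak2 and Fyn rose from 28.4 to 71.1 and from 41.6 to 107 CPM in wild type and from 28.9 to 69.6 and from 42.6 to 119 in Egr2KO, with differences of -0.06 (-0.32 to 0.20) and 0.12 (-0.12 to 0.37).

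Single libraries stood apart for a few genes. Retnlg, a neutrophil marker, held 645 and 774 reads in wild-type IL-4 replicates 2 and 3, 347 in Egr2KO IL-4 replicate 3 and at most 8 in each other library; no test was run on this. These reads did not follow those of the related Retnla, of which wild-type IL-4 replicate 1 held 39104 with 2 Retnlg reads, and Egr2KO IL-4 replicate 3 held 16050. Lars2 ranged from 51.5 to 442 CPM over the 12 libraries.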
